A study of Homo sapiens with 2 samples.

How the data were processed

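RNA was sequenced from 2 libraries labelled as BT549, a human breast cancer cell line. The labels name the SIK1 genotype, wild-type (WT) in 1 library and S435D in the other, taken here as overexpressed constructs. The deposited table holds RPKM (reads scaled to gene length and library depth) for 43337 genes in both libraries, with chromosome, start, end, strand and length of each gene, per the file headers. The aligner, the program that counted reads, the strand setting, the genome build, the annotation and the library protocol are not given in the sources used here.

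Whole reads were recovered from the values, since RPKM times gene length was a whole multiple of a single step in each library. With a tolerance of 0.01 reads, 100% of the values above 0 came out whole, and the recovered reads summed to 22366506 in the WT library and 23520828 in the S435D library, the same totals that the step sizes imply. The RPKM values are therefore relative to reads assigned to the listed genes. A single read on a gene of 2 kb equals 0.0224 RPKM in the WT library and 0.0213 in the S435D library. Reads that overlap several genes appear to be counted for each of them: the readthrough gene NME1-NME2 holds 16659 reads in the WT library, where NME1 and NME2 hold 8304 and 8825. The gene names of 28 genes had been turned into dates and were left as they are. Positions match the human assembly of GENCODE release 29 (GRCh38), where 26475 of 27994 genes matched by symbol and position had the same start and end (94.6%), and gene types came from that annotation or from RefSeq.

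The log2 ratio was log2 of (S435D RPKM plus 0.5) over (WT RPKM plus 0.5), which understates differences of genes at low levels. Genes with a mean of at least 1 RPKM over both libraries counted as expressed. Folds are ratios of RPKM without a pseudocount, with exact conditional binomial (Clopper-Pearson) 95% intervals from the recovered reads, and a count of 0 was taken to allow up to 3 reads. With 1 library per group there was no test, no p-value and no estimate of spread between replicates, so a fixed rule of size (2-fold) was used as a description of these libraries. For each gene list the median log2 ratio of its expressed members was set against the medians of 10000 random lists of the same size, matched on mean expression in 20 bins, for lists with at least 5 expressed members. The procedure was tested on simulated data for 10178 genes, drawn from the mean levels and depths of these libraries. Of 50 genes simulated at fold 3, 100% passed the 2-fold rule, and 94% of 50 genes at the inverse fold did. Of 100 unshifted lists 4 fell outside the central 95%, and 20 of 20 lists shifted by 0.15 were found above it. The simulation held counting error only and lists of genes drawn at random. It does not show how smaller lists, or lists whose genes move together, behave.

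The groups, the rule of size, the gene lists, the rule for named genes and the alternative settings were fixed before the data were examined. Named genes were SIK1, SIK2, SIK3, AKT1 and STAT3, the 15 genes with the largest and the 15 with the smallest log2 ratio at a mean of at least 5 RPKM, 2 to 4 of the 4 members farthest from 0 in each list (1 where a single member was expressed), and the 3 most abundant genes of each library; other genes named were chosen after their values were seen. The table gives no gene type, so protein-coding genes were taken by symbol, leaving out clone, LOC, MIR, SNOR, SCARNA, RNU, LINC, antisense and pseudogene-type names. A name ending like a pseudogene was left out only if the annotation did not call it protein-coding, a refinement made after the table had been seen. This rule also lets 217 expressed non-coding or unannotated genes in. A restriction to annotated protein-coding genes was therefore added after the values had been seen and is given beside the rule as planned. XIST and Y-linked genes are not reported.

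Alternatives were pseudocounts of 0.1 and 1 RPKM, no filter on low values and a mean of at least 5 RPKM, centring on the median, rescaling both libraries, whose RPKM summed to 399824 and 417363, to the same larger total, which also lets more genes past the filter and weakens the pseudocount, scaling by a trimmed mean of log ratios, genes with a unique symbol and at least 500 bases, recovered reads with at least 20 in total, a 1.5-fold rule, 50 expression bins and the mean of list members. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.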

Results

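Gene expression was measured by RNA sequencing in cells labelled BT549, an identity taken from the sample labels alone. BT549 is a human cell line derived from a triple-negative breast cancer, a tumour type that lacks the oestrogen and progesterone receptors and HER2 amplification. From their genotype labels, the cells were taken to overexpress SIK1, a serine/threonine kinase related to AMPK. The construct was either the wild-type protein (WT) or S435D, in which aspartate replaces a serine, an exchange commonly used to imitate phosphorylation. There was 1 library per construct, so no difference has a replicate check, no test was run, and all intervals cover counting error only. The WT library held 22366506 assigned reads and the S435D library 23520828. Cells without a SIK1 construct were not analysed here.

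The series title links phosphorylation of SIK1 by Akt1 to STAT3 signalling, so SIK1, its relatives, AKT1 and STAT3 were read first. SIK1 (chromosome 21, 43414515 to 43427128, minus strand) reached 380 RPKM (reads scaled to gene length and to library depth) in the WT library and 422 RPKM in the S435D library, a fold of 1.11 (95% counting interval 1.09 to 1.12). It was 162 times the level of SIK2 in the WT library and 175 times in the S435D library. SIK2, a paralogue that also phosphorylates CRTC coactivators and overlaps PPP2R1B, stood at 2.35 and 2.41 RPKM. SIK3, the remaining member of the family, stood at 1.81 and 1.77 RPKM. AKT1, the kinase named in the series title, was at 8.82 RPKM in the WT library and 9.42 in the S435D library (fold 1.07, 1.01 to 1.13), and its reads overlap a clone-named gene. STAT3, the transcription factor downstream of IL-6 family cytokines, was at 5.01 and 4.57 RPKM (fold 0.912, 0.834 to 0.998). Reads of SIK1 are uncertain in level, because a clone-named gene elsewhere on chromosome 21, CH507-42P11.8, has a near-identical sequence and was counted beside it at 450 and 522 RPKM. RPKM values do not tell the construct from the cell's own SIK1.

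The genes regulated by STAT3 were next compared between the libraries. Of 32 listed STAT3 target genes, 17 had a mean of at least 1 RPKM, 8 of them higher and 9 lower in the S435D library, with a median log2 ratio of -0.037. The farthest from 0 were all lower in the S435D library. TWIST1, a transcription factor of mesenchymal cells, had a fold of 0.759 (0.608 to 0.945), MMP2, a gelatinase, 0.792 (0.699 to 0.898), VEGFA, an angiogenic growth factor, 0.851 (0.791 to 0.915), and MCL1, an inhibitor of apoptosis, 0.870 (0.812 to 0.933). Other targets were named after their values were seen. MYC was at 37.4 RPKM in the WT library and 34.7 in the S435D library, and BIRC5, which encodes survivin, at 78.6 and 80.0 RPKM. SOCS3, a feedback inhibitor induced by STAT3, had 62 reads in the WT library and 53 in the S435D library, and BCL3 had 73 and 58. IL6 had 0 reads in both libraries, which allows up to 3 reads in each. Among cytokine receptor and JAK-STAT components, 17 of 36 were expressed, 7 higher and 10 lower, with a median log2 ratio of -0.0092. SOCS7 had a fold of 0.788 (0.687 to 0.905), STAT2 0.888 (0.732 to 1.08) and JAK1 1.02 (0.930 to 1.12). JAK1 and the genes that follow were named after their values were seen. Larger differences lay among members below a mean of 1 RPKM and rest on few reads. JAK2 had 25 reads in the WT library and 55 in the S435D library, LIF 17 and 41, and STAT5A 3 and 14. SOCS1 went the other way, with 23 and 12 reads. The median of the STAT3 targets lay at percentile 33.4 of 10000 random lists of the same size and expression, and that of the JAK-STAT components at percentile 60.3. At a mean of at least 5 RPKM both medians changed sign, to 0.025 and 0.026, and that of the JAK-STAT components also did without a filter, at 0.0012, and when centred or scaled by a trimmed mean, at 0.010 and 0.016.

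The libraries were then compared over all genes. By a rule that takes gene type from the symbol, 2 of 10178 expressed genes were at least 2-fold higher in the S435D library and 4 at least 2-fold lower, and all of them were short and not annotated as protein-coding. They are named here after their values were seen. VTRNA1-2, a vault RNA, had 1 read in the WT library and 4 in the S435D library (fold 3.80, 0.376 to 187), and HOTTIP_1, a conserved part of a long non-coding RNA, had 0 and 5. Lower in the S435D library were TP53TG1_1 with 22 and 9 reads (0.389, 0.158 to 0.879), Vax2os1_3 with 10 and 1 (0.0951, 0.00219 to 0.668), PVT1_3 with 6 and 1 (0.158, 0.00345 to 1.31), and snoZ196 with 4 and 0. Among the 9961 genes that are also annotated as protein-coding, a restriction added after the values had been seen, 0 were 2-fold higher and 0 lower, and the log2 ratio ran from -0.82 to 0.85. The median log2 ratio over the 10178 genes was -0.020 with an interquartile range of -0.099 to 0.059, and 94.5% lay within 1.2-fold of equality. Pearson's r of log2 levels was 0.997 across genes, which are not independent replicates. In libraries simulated from these levels, 2 of 9978 unchanged genes passed the 2-fold rule by counting error alone.

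**Figure D1:**
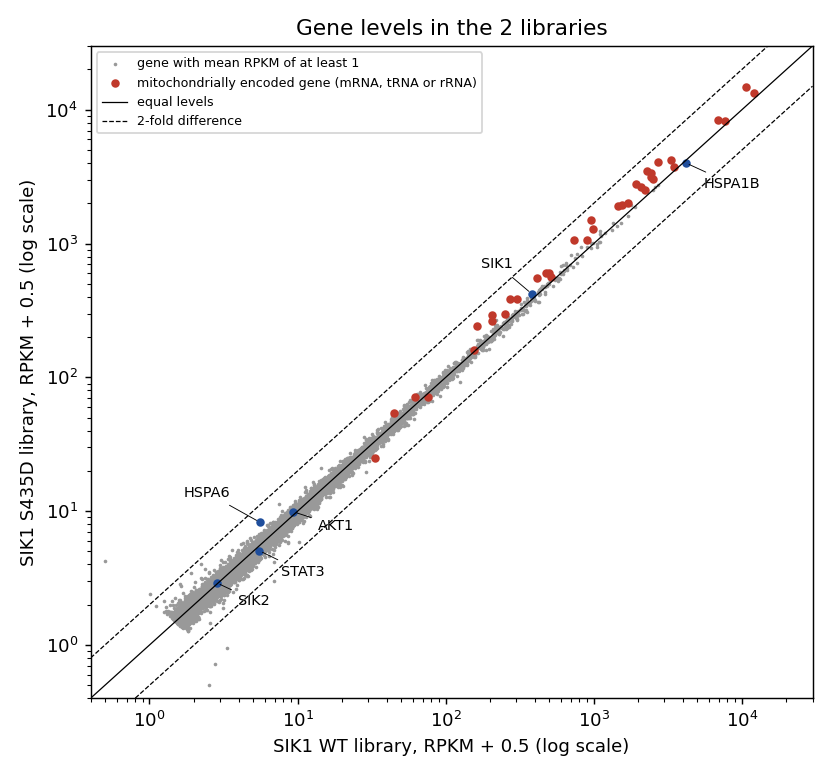
Level of each gene in the SIK1 WT library (horizontal) and in the SIK1 S435D library (vertical), as RPKM plus 0.5 on log axes, with genes of a mean of at least 1 RPKM in grey, mitochondrially encoded genes in red and selected genes in blue. Points follow the line of equal levels, SIK1 at 380 and 422 RPKM included.

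The 15 genes with the largest ratio at a mean of at least 5 RPKM were led by mitochondrial transfer RNAs. MT-TN had a fold of 1.56 (1.46 to 1.66), MT-TK 1.53 (1.47 to 1.60), MT-TC 1.49 (1.44 to 1.55), MT-TY 1.46 (1.39 to 1.53), MT-TA 1.45 (1.35 to 1.57), MT-TW 1.42 (1.23 to 1.64), and MT-TH 1.42 (1.25 to 1.61), MT-TC and MT-TY sharing a base. MT-TS2 was at 161 RPKM in the WT library and 241 in the S435D library, and MT-TE at 415 and 554 RPKM. RN7SL2 and RN7SL1, which encode near-identical copies of the RNA of the signal recognition particle, had folds of 1.56 (1.07 to 2.29) and 1.47 (1.13 to 1.93), and RN7SL1 overlaps RPS29. HSPA6, a stress-induced HSP70 chaperone with close paralogues, was at 5.05 RPKM in the WT library and 7.78 in the S435D library (fold 1.54, 1.32 to 1.80). MT-ATP8 had a fold of 1.39, MT-ND4L 1.37 and APOM, an apolipoprotein of high-density lipoprotein that overlaps BAG6, 1.37 (10.7 and 14.6 RPKM).

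The 15 genes with the smallest ratio included fragments of the long non-coding RNAs TUG1, NEAT1 and TP53TG1. TUG1_2 had 19 reads in the WT library and 11 in the S435D library, NEAT1_2 had 15 and 9, NEAT1_3 had 102 and 71, and TP53TG1_2 had 33 and 23, all inside their host genes. BCYRN1, a small cytoplasmic RNA, had a fold of 0.745 (0.655 to 0.846). The pseudogenes RBM8B and SERHL had 0.644 (0.463 to 0.891) and 0.733 (0.609 to 0.882) and overlap C14orf39 and RRP7A, and the transfer RNA MT-TF, with 52 and 41 reads, had 0.750 (0.485 to 1.15). GOLGA6L9 at 0.675 (0.610 to 0.747), GOLGA8A at 0.731 (0.678 to 0.788) and AGAP9 at 0.710 (0.611 to 0.824) belong to families with near-identical copies, which leaves their levels uncertain. TMSB15A, an actin-binding thymosin, had 0.700 (0.503 to 0.970) and FNDC10 0.723 (0.606 to 0.861). WRB, which takes part in inserting tail-anchored proteins into the endoplasmic reticulum and overlaps LCA5L, had 0.744 (0.677 to 0.817). HOXA10-HOXA9, a readthrough transcript whose reads overlap both HOX genes, had 0.754 (0.640 to 0.888).

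Restricting the rule to annotated protein-coding genes, after the values had been seen, brought in further genes. Higher in the S435D library were SMC5, a subunit of the SMC5/6 complex of DNA repair (fold 1.29, 1.18 to 1.42), NDUFB4, a nuclear-encoded subunit of respiratory complex I (1.28, 1.13 to 1.44), ADRA2C, an adrenergic receptor (1.29, 1.08 to 1.55), and TMEM141 (1.29, 1.18 to 1.40). TMEM79 at 1.36, NME3 at 1.31 and EFNA4 at 1.28 overlap other genes with reads, as does TMEM141. Lower were ID2, an inhibitor of helix-loop-helix transcription factors (0.750, 0.661 to 0.850), OGT, the enzyme that adds O-linked N-acetylglucosamine to proteins (0.757, 0.702 to 0.816), POLR3C, a subunit of RNA polymerase III (0.755, 0.672 to 0.848), and DNTTIP2 (0.755, 0.709 to 0.804). PSMC2, an ATPase of the proteasome, at 0.769, PTRH2 at 0.762 and FBXL14 at 0.751 overlap other genes with reads. PIGY had 32 and 25 reads, and its interval of 0.422 to 1.29 includes 1.

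The mitochondrially encoded protein genes were higher in the S435D library as a group. All 13 had a fold above 1 with a counting interval above 1, from 1.07 (1.06 to 1.07) for MT-CO3 to 1.39 (1.38 to 1.41) for MT-ATP8, and their median log2 ratio was 0.31. They encode subunits of the respiratory chain and of ATP synthase. MT-ND5 was at 1464 RPKM in the WT library and 1899.5 in the S435D library, and MT-CYB at 2069 and 2662 RPKM. MT-CO1 had a fold of 1.24 (1.23 to 1.25) and MT-ATP6 1.11 (1.11 to 1.12). MT-ATP6, MT-ATP8 and MT-CO3 were the 3 most abundant genes of the WT library, at 12038, 10659 and 7737 RPKM, and MT-ATP8, MT-ATP6 and MT-ND3 those of the S435D library, at 14839, 13419 and 8318 RPKM. Of 22 mitochondrial transfer RNAs, a group added after the values had been seen, 20 were higher and 2 lower, with a median log2 ratio of 0.36. Some lie beside protein genes: MT-TK ends at base 8364 and MT-ATP8 starts at 8366. Reads that span both may be counted for each, so these groups are not independent. The ribosomal RNAs MT-RNR1 and MT-RNR2 had lower log2 ratios, 0.053 and 0.18, and the counting interval of MT-RNR1 (fold 1.04, 0.989 to 1.09) includes 1. Reads from the mitochondrial chromosome made up 4.32% of the WT library and 5.15% of the S435D library. In contrast, 17 of 42 nuclear-encoded oxidative phosphorylation genes were higher and 25 lower, with a median log2 ratio of -0.025, which scaling by a trimmed mean turned to 0.0021. UQCRC2, a complex III subunit, had a fold of 0.841 (0.770 to 0.918) and COX5B, of complex IV, 165 and 190.2 RPKM. The median of the mitochondrial list lay at percentile 100 of its random lists, and it stayed above 0 under each scaling tried. Genes of the random lists were drawn singly, so the percentile does not allow for a shift shared by all mitochondrial genes. MT-ATP8 with MT-ATP6 and MT-ND4L with MT-ND4 share bases, and the median was 0.27 without those 4 genes.

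**Figure D2:**
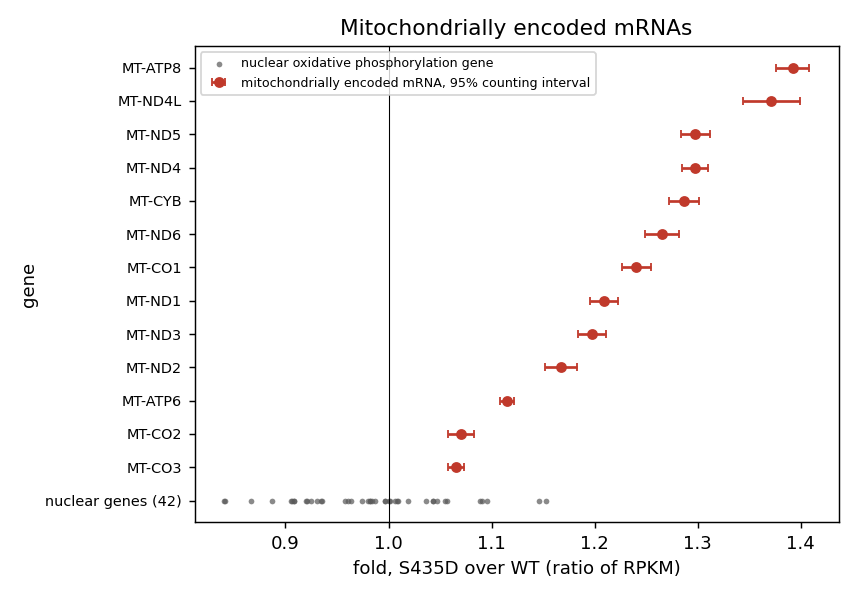
Fold of each of the 13 mitochondrially encoded protein genes between the S435D and the WT library (ratio of RPKM), with 95% counting intervals, and of 42 nuclear oxidative phosphorylation genes as grey points. The mitochondrial folds run from 1.07 to 1.39.

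Of the 36 gene lists, 32 had at least 5 expressed members and so a percentile. The mitochondrial list was the only one outside the central 95% of its random lists under the main settings, against 1.6 lists expected by chance. That expectation and the percentiles treat genes as independent. Mitochondrial genes may shift together with the mitochondrial share of a library, so for them neither measures chance. The random lists were not matched on GC content. Across bins of GC content, the median log2 ratio ran from -0.055 (46.8 to 49.9% GC) to 0.029 (62.1 to 74.5% GC). List medians of that size may therefore partly reflect GC content, which was not tested. The largest absolute median among the other lists with a percentile was 0.089, for the MEF2 factors and class IIa deacetylases, the latter known substrates of SIK kinases. Of 6 expressed members, 5 were higher, with MEF2B at a fold of 1.27 (0.987 to 1.65) and HDAC5 at 1.06 (0.987 to 1.13), at percentile 97.0, and the list lay outside the central 95% without a filter on low values and with the mean of members. The 7 expressed CREB and CRTC target genes had a median of -0.047 (percentile 24.8), with ATF3 at a fold of 1.12 (1.05 to 1.19) and CREM at 0.898 (0.801 to 1.01), and with the 5 members at a mean of at least 5 RPKM the median turned to 0.10 (percentile 98.2), SIK1 itself being among the 5. The 14 expressed AMPK-related kinases had a median of -0.026 (percentile 48.0), with MARK3 at 0.837 (0.765 to 0.916), and their median likewise turned to 0.10 (percentile 98.0) with 5 members at that level, SIK1 among them. Of 15 PI3K-AKT pathway components, 5 were higher and 10 lower (median -0.024, percentile 48.2), with TSC2, a negative regulator of mTORC1, at 3739 and 4512 reads, and PIK3R3, a regulatory subunit of PI3K, at 0.880 (0.730 to 1.06). FOXO targets had a median of -0.049 (percentile 26.2), with SESN1 at 0.689 (0.564 to 0.841) and CCNG2 at 0.829 (0.679 to 1.01).

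**Figure D3:**
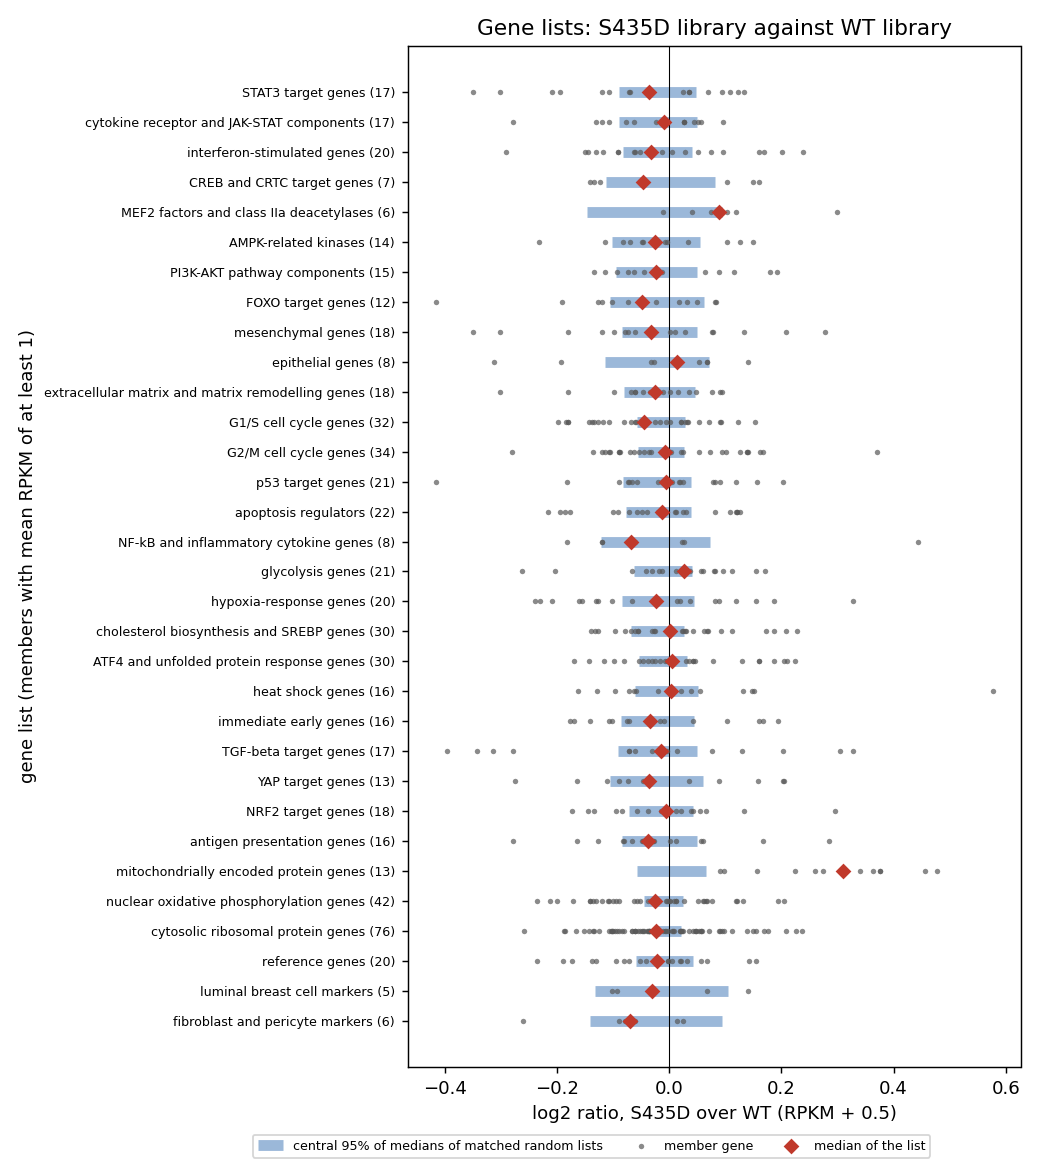
Log2 ratio of each expressed member (grey points) and the list median (red diamonds) for the 32 lists with at least 5 expressed members, against the central 95% of medians of matched random lists (blue bars), with the number of expressed members in brackets. The mitochondrial list, with a median of 0.31, lies outside its bar.

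Cell cycle, stress and metabolic lists with a percentile stayed inside the range of random lists under the main settings, with medians near 0. Scaling by a trimmed mean turned the medians of the G2/M, p53, apoptosis, hypoxia, NRF2, ribosomal and reference lists above 0, and rescaling both libraries to the same larger RPKM total turned those of the ATF4, heat shock, glycolysis and cholesterol lists below 0. Of 32 G1/S genes, 12 were higher and 20 lower (percentile 7.97), with UHRF1, a partner of DNA methyltransferase, at 0.879 (0.848 to 0.912) and MCM6, a subunit of the replicative helicase, at 0.880 (0.831 to 0.933). Of 34 G2/M genes, 14 were higher and 20 lower (percentile 61.9), with the spindle genes ASPM at 1.34 (1.22 to 1.48) and DLGAP5 at 0.818 (0.755 to 0.887), and TOP2A, a DNA topoisomerase, at 1.12 (1.09 to 1.15). The p53 targets lay at percentile 70.6, with PPM1D at 3.13 and 3.68 RPKM and MDM2, the ubiquitin ligase of p53, at 1.14 (1.03 to 1.27), and apoptosis regulators at 56.3, with BCL2L2 at 0.877 (0.783 to 0.981). Of 30 ATF4 and unfolded protein response genes, 17 were higher and 13 lower (percentile 75.9), with the amino acid transporter SLC7A5 at 1.17 (1.12 to 1.23) and DDIT4 at 1.14 (1.09 to 1.19). The heat shock genes lay at percentile 63.2, with HSPA8 at 0.894 (0.880 to 0.907) and HSPH1 at 1.11 (1.07 to 1.15), and the NRF2 targets at 60.0, with NQO1 at 1.27 (1.05 to 1.54) and PRDX1 at 0.886 (0.861 to 0.913). Glycolysis genes, 14 higher and 7 lower, lay at percentile 92.4, with LDHB at 0.833 (0.814 to 0.852) and the aldolase gene ALDOC at 1.14 (0.981 to 1.32). Hypoxia-response genes lay at percentile 47.5, with BHLHE40 at 1.28 (1.12 to 1.47), and cholesterol biosynthesis and SREBP genes at 80.0, with PMVK at 1.16 (1.08 to 1.24) and DHCR7 at 1.15 (1.03 to 1.27). Of 76 cytosolic ribosomal protein genes, 32 were higher and 44 lower (percentile 3.16), with RPL11 at 0.835 (0.810 to 0.861) and RPS2 at 1.18 (1.17 to 1.19), and was outside the range at 50 expression bins and at a mean of at least 5 RPKM. These genes have near-identical pseudogenes, as has EEF1A1, which leaves their levels uncertain. The reference genes lay at percentile 29.3, with EEF1A1 at 0.849 (0.839 to 0.859) and TBP at 0.874 (0.808 to 0.946). Of 4 expressed replication-dependent histone genes, too few for a percentile, 3 were higher and the median log2 ratio was 0.13, with HIST1H1E at 19 and 40 reads and HIST1H2BK at 116 and 143.

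Signalling and identity lists were inside that range as well, and centring or a trimmed mean turned the sign of the TGF-beta list, and the rescaling to a larger total that of the epithelial list. Interferon-stimulated genes lay at percentile 35.1, with IFIT1 at a fold of 0.806 (0.726 to 0.894) and UBE2L6 at 4.78 and 5.73 RPKM, antigen presentation genes at 24.9, with TAP2 at 0.812 (0.741 to 0.891) and PSMB10 at 4.83 and 5.99 RPKM. Immediate early genes lay at percentile 31.2, with IER2 at 0.878 (0.787 to 0.980) and ZFP36 at 0.872 (0.683 to 1.11), and YAP targets at 37.0, with LATS2 at 0.770 (0.621 to 0.955) and AMOTL2 at 1.18 (1.02 to 1.38). Of 17 TGF-beta targets, 6 were higher and 11 lower (percentile 58.9), with BMP4 at 0.756 (0.617 to 0.924). Of 35 NF-kB and inflammatory cytokine genes, 8 were expressed (percentile 18.4), with CCL5 at 1.42 (1.09 to 1.85) and TNFAIP3 at 0.840 (0.667 to 1.06). Mesenchymal genes lay at percentile 34.7 and matrix genes at 41.0, with SPARC at 0.878 (0.818 to 0.944), and epithelial genes at 76.3, with OVOL2 at 0.778 (0.620 to 0.975). VIM, the mesenchymal intermediate filament gene, was at 116 RPKM in the WT library and 113 in the S435D library, while FN1, which encodes fibronectin, was at 1.16 and 1.17 RPKM.

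Markers of breast and other cell types were read to describe what the libraries hold. Of 16 basal breast markers, 1 was expressed, ITGA6 at 1.23 RPKM in the WT library and 0.996 in the S435D library. EGFR had 0.740 and 0.734 RPKM, CAV1 0.964 and 0.989 RPKM, and KRT5 had 0 and 1 reads. Of 16 luminal breast markers, 5 were expressed, with KRT8 at 45.5 and 47.7 RPKM, KRT18, which overlaps it, at 37.5 and 41.4 and GATA3 at 2.49 and 2.30, and ESR1, the oestrogen receptor gene, had 1 and 0 reads. Of 18 immune markers 3 were expressed, among them CD68 at 3.41 and 3.59 RPKM and CORO1A at 1.60 and 1.68, of 12 endothelial markers 1, EGFL7, at 12.8 and 13.4 RPKM, and of 15 fibroblast and pericyte markers 6, with PDPN at 7.39 and 6.09 RPKM and MCAM at 9.39 and 8.79. The luminal list lay at percentile 37.4 and the fibroblast list at 21.3. CD44, a surface glycoprotein used as a marker of mesenchymal breast cancer lines and looked up after the data had been seen, had 8 reads in each library.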

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

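The tests on GC content, transcript length and a common factor for the mitochondrial genes, and that on scaling for the cell line genes, were chosen after the result was seen, while the bounds for the shared sequence of SIK1 were set beforehand.

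A gene outside the comparisons drew more reads than SIK1 itself: CH507-42P11.8, at 6111134 to 6123739 on chromosome 21, had 48414 reads in the WT library and 58978 in the S435D library. Its position is that of SIK1B in the GENCODE annotation. Reads shared between near-identical copies may be the source: 94.2% of the 31-base words of the SIK1 transcript also occur in that of SIK1B, just short of the 95% set in advance as the bound for this explanation, so the case stays open. No biological explanation was tested. Summing both genes gave a fold of 1.14 (95% counting interval 1.13 to 1.15) in place of 1.11 for SIK1 alone.

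The mitochondrially encoded protein genes stood apart from the other genes. GC content argues against itself as the whole cause, since 3018 nuclear genes in the same GC range had a median log2 ratio of -0.039. Short transcripts do so too, since 714 nuclear genes in the same length range had a median of 0.00096. A factor common to all mitochondrial protein genes may remain, and cannot be told apart from gene-specific differences. The members' spread was 1.38 times that of nuclear genes at 100 RPKM or more, under the bound set for a common factor. The counting intervals of MT-CO3 (1.06 to 1.07) and MT-ATP8 (1.38 to 1.41) do not overlap. They cover counting error only, and nuclear genes at that level also spread beyond it. The gap therefore cannot decide against a common factor. The ribosomal RNAs MT-RNR1 and MT-RNR2 had lower log2 ratios, 0.053 and 0.18, and are not protein genes. The SIK1 construct stays open as an untested explanation, because each construct has 1 library.

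Of 38 genes listed as typical of mesenchymal breast cancer lines, 14 were under 1 RPKM in both libraries and 12 were at 10 RPKM or more, and of the 21 whose level had not been looked at, 4 were under 1 RPKM, TGFBI with 1 and 0 reads among them, while CD44 with 8 reads in each library and AXL with 17 and 20 had been looked at first. The test set for the scaling of the values could not have come out otherwise. None of the listed genes under 1 RPKM could hold more than 294 recovered reads at that level, under the bound set for this explanation. Their recovered reads had a median of 8 per library. Because these genes were picked for their low RPKM, that count cannot decide on scaling as the source. RNA of cells other than those the label names is a candidate explanation: those 21 genes had a median of up to 6.97 RPKM, under the bound of 10 set beforehand, although 10 of them were at 10 RPKM or more, with S100A11 at 235 and 242 RPKM and TPM2 at 298 and 306. Among genes taken as protein-coding, that median lay at percentile 76.4 in the WT library and 77.8 in the S435D library. Of the 19443 genes taken as protein-coding, 10178 were expressed. As a group these 21 genes were therefore not low against a set that includes unexpressed genes. Their place among expressed genes was not computed. HEK293-derived cells are a candidate source, since 7 listed genes of that line not looked at before had a median of at least 16.4 RPKM, 4 of them at 10 RPKM or more, such as UCHL1 at 61.1 and 60.0, and 3 below, HOXD10 at 9.38 and 7.58, HOXA10 at 5.44 and 4.43 and IGF2BP3 at 3.58 and 3.65, after HSPA1B, CKB and NEFM, the most abundant apart from HSPA1A, had been seen at 4183, 272 and 87.7 RPKM in the WT library. This is a hypothesis only and no biological explanation was tested: no reference profile of BT549 or HEK293 was used here, so how many of the listed genes BT549 itself expresses is not known, the lists were drawn up after part of the levels had been seen, and 15 of the 38 mesenchymal-line genes and 2 of the 19 HEK293 genes are also in the 36 other lists. The median of the 7 HEK293 genes lay at percentile 88.1 in the WT library and 88.2 in the S435D library. Among these 7, HOXA10, HOXC9 and HOXD10 lie beside HOXA9, HOXC10 and HOXD13, whose levels had been seen, so they are not independent of those.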

How the results depend on the processing

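The restriction to annotated protein-coding genes, the mitochondrial list without overlapping genes and the sum of SIK1 with its copy were chosen after the data were seen, and the other alternatives were planned. No paired analysis was possible because each construct has 1 library, and for the same reason no library could be left out in turn. The counts of genes past 2-fold, 2 higher and 4 lower, rest on few reads and vary with the setting. They were 6 and 5 with a pseudocount of 0.1 RPKM, 1 and 4 with 1 RPKM, 9 and 11 without a filter on low values, 7 and 14 after rescaling to the same larger total, and 0 and 0 at a mean of at least 5 RPKM, with unique symbols and at least 500 bases, and with annotated protein-coding genes. Recovered reads gave 46 and 67, where counting error alone gave means of 29.6 and 30.2, and a 1.5-fold rule gave 14 and 12 (26 in all), where counting error alone gave 13.9 and at most 22. The median of all genes was -0.016 without a filter and -0.080 after rescaling. Rescaling changes several things at once: the shift between the libraries is -0.062, while the raised values let 12035 genes past the filter in place of 10178 and weaken the pseudocount, and their parts were not separated. The number of gene lists outside the central 95% was 3 without a filter (adding MEF2 and histone genes), 4 at a mean of at least 5 RPKM (adding CREB, AMPK-related and ribosomal genes), 2 after rescaling (histone), 2 with 50 bins (ribosomal) and 2 with the mean of members (MEF2). After rescaling the STAT3 targets were at -0.12 with 22 members and the JAK-STAT components at -0.070 with 26, in place of 17 each. The mitochondrial list stayed above 0 under all alternatives run, at 0.33 when centred, 0.25 after rescaling, 0.34 with a trimmed mean, 0.29 as a mean and 0.27 without overlapping genes. SIK1 was likewise higher in the S435D library throughout, at 0.17 when centred, 0.087 after rescaling, 0.18 with a trimmed mean and 0.18 summed with its copy. List medians near 0 changed sign: 6 of 36 when centred, 6 after rescaling, 10 with a trimmed mean, 8 without a filter, 8 of 34 at a mean of at least 5 RPKM and 4 as a mean. Of the other gene list values, 23 moved beyond counting error (9 toward higher in the S435D library, 14 toward lower) and 305 did not, and of the values of single genes 27 moved (16 and 11) and 253 did not. Where a list's members drop out under a stricter filter, fewer genes enter its median; the cause of the other shifts was not tested. Depth limits the lowly expressed genes: those past 2-fold by recovered reads had a median of 31 reads over both libraries.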

Other observations

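The list of BMP-responsive genes was drawn up after ID2, BMP4 and ID1 had been seen to be lower in the S435D library, and its test used the members not looked at before. Of those, ID3, SMAD6, SMAD7 and BAMBI are also in the TGF-beta list and ID4 in the CREB list. The test is therefore not independent of those lists.

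Genes at high levels in both libraries, named after their values were seen, included HSPA1B at 4183 RPKM in the WT library and 4006 in the S435D library and HSPA1A at 689 and 691 RPKM, stress-inducible HSP70 genes with near-identical sequences, so that the split between them is uncertain. NEFM, a neurofilament gene, was at 87.7 and 82.8 RPKM, NEFL at 39.2 and 34.6 and TUBB2B, a tubulin gene, at 80.2 and 75.2. CDKN2A, a cell cycle inhibitor locus, was at 80.2 and 83.7 RPKM. The homeobox gene HOXC9 was at 26.6 and 28.1 RPKM, HOXD13 at 15.9 and 15.2 and HOXC10 at 14.8 and 15.6.

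A lower level of BMP-responsive genes as a group in the S435D library was tested as a hypothesis and not found. The 11 expressed members not looked at before had a median log2 ratio of -0.061, at percentile 18.9 of matched random lists, and 6 of 11 were lower. SMAD6 had a fold of 0.793 (95% counting interval 0.697 to 0.901) and MSX1 0.822 (0.717 to 0.941), whereas ID3, an inhibitor of helix-loop-helix factors like ID2, was higher at 1.24 (1.12 to 1.38).

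Differences between the libraries were larger than counting error at high levels. Among 465 genes with a mean of at least 100 RPKM, the SD of the log2 ratio across genes was 0.14, where counting error alone gave 0.026. It was 0.10 over the 443 of them that are annotated as protein-coding and 0.090 over the 430 of those that are nuclear. Over all 10178 expressed genes, 25.6% of the counting intervals excluded a fold of 1, where counting error alone would give 5%. Without a second library of either construct, these differences were not set against the spread between cultures.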
